A study of Mus musculus with 6 samples.

How the data were processed

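RNA from 6 sorted cell samples was measured, 3 from an Itgav-negative Tie2-negative and 3 from an Itgav-low Tie2-positive population of limb skeletal cells of mice at postnatal day 3. Per the labels' protocols, the RNA was amplified in a double round before labelling and hybridised to Affymetrix Mouse 430 2.0 arrays, which were scanned with GCOS 1.1.1. The labels give the genotype as wild type and elsewhere speak of GFP-labelled mice, and which holds for these samples was not settled here. The deposited table holds 1 log2 value per probe set and array, between 2.56 and 14.78. That the deposited scale is log2 was taken from the range of the values. How the authors summarised and normalized the deposited values is not given in the sources used here. No array pair held identical values (0 pairs).

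The table had 45101 probe sets, of which 64 array controls were left out of the tests. Gene names came from a table of the platform's annotation. Of the other 45037 probe sets, 34945 carried 1 gene symbol, 932 carried several and were not named, and 9160 were unnamed here. Symbols were looked up by gene ID in a RefSeq table (GRCm38.p6), which held 34754 of the 34945 and changed 0 symbols. Each of 18193 genes was represented by the probe set with the highest mean over the 6 arrays. Of genes with more than 1 probe set (9010), 51 had another probe set called the opposite way to the one used, none of them a called gene. No coordinates are given, because the array tables name no genome build.

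The arrays' medians differed by up to 0.08 and their 75th percentiles by up to 0.27. Since the latter passed the preset limit of 0.1, the values were quantile normalized. The 75th percentiles ran from 7.26 to 7.33 in the Itgav-negative Tie2-negative and from 7.45 to 7.53 in the Itgav-low Tie2-positive arrays. The normalization thus also removed a difference that went with the populations. The comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean trend), all 6 arrays, no covariates, two-sided, with Benjamini-Hochberg adjustment over 18193 genes and a threshold of 0.05. The median log2 change over all genes was -0.11. For arrays there is no read depth, and the number of arrays limits the precision.

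The choices in this and the next paragraph were made before the data were examined, unless said otherwise. The 31 gene lists were written from textbook knowledge of endothelial, stromal, skeletal and blood cells and hold 484 entries, of which 451 were measured. Each list was tested with camera at a preset correlation of 0.01, and beside it with an estimated correlation (statmod 1.5.0) and with fry, each adjusted over the 31 lists. Named genes followed a rule. Among called genes whose populations did not overlap and whose higher mean lay above the median of all gene values (6.55), the rule took the 12 largest changes in each direction. It also took every sort marker and up to 3 called genes above that level with the largest change per list. For a list with no such gene it took the 2 with the highest mean.

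The alternatives were the replicate number as a block, the values as deposited, arrays centred on their medians, a filter at the 40th percentile of mean level, and the mean of all probe sets of a gene. Others were leaving out probe sets with the suffix x_at or s_at, which can match several transcripts, testing all 45037 probe sets, eBayes without the trend or with robust estimation, array weights, leaving out each array in turn, and lists without genes that another list holds. Other offsets before taking logs, meant for values on a linear scale, were not run, because the values are on a log scale. Leaving out Tie2-positive replicates 2 and 3 together was added after seeing the data. In that fit the lone Tie2-positive array is assumed to vary like the other population.

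The procedure was tested on simulated data of 18193 genes in 3 and 3 arrays, with 200 genes changed by known amounts, in 5 draws. It recovered 24.8% of genes changed by 1, 83.0% of those changed by 2 and 96.7% of those changed by 3 on the log2 scale. Of 737 calls, 57 (7.73%) were false, somewhat above the nominal 5%. All 5 planted lists were called, and 0 of 150 random lists. The simulated genes varied independently of one another and with the same spread in both populations. The simulation therefore does not cover lists of correlated genes, and the estimated correlation of the real lists ran up to 0.917.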

Results

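Gene expression was measured on 6 single-colour Affymetrix Mouse 430 2.0 arrays, each hybridised with RNA from cells sorted out of the limb skeleton of mice at postnatal day 3. Limbs of a litter were pooled and digested with collagenase, and the released cells were stained and separated by flow cytometry. The first population, called Tie2-negative here, was titled as lacking CD45 (the pan-leukocyte antigen, encoded by Ptprc), Ter119 (an antigen of the erythroid lineage), integrin alpha V (Itgav) and Tie2 (the angiopoietin receptor, encoded by Tek). The second, called Tie2-positive here, was titled as lacking CD45 and Ter119, low for integrin alpha V and positive for Tie2. Each population had 3 arrays. The dashes in the titles were read as minus signs. The sources used here do not say whether the 3 samples of a population came from separate litters, so the p-values measure the spread between these samples, which may be technical, and the number of arrays limits the precision. The series concerns the stroma of neonatal bone marrow, and its single comparison asks which transcripts separate the Tie2-positive from the Tie2-negative fraction of the limb skeleton. All changes are given as Tie2-positive minus Tie2-negative on the log2 scale, after quantile normalization, with n = 3 per population.

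The Tie2-positive arrays differed among themselves more than the Tie2-negative arrays did. Over 18193 genes, correlations within the Tie2-negative population ran from 0.969 to 0.983, and within the Tie2-positive population from 0.898 to 0.980. The first principal component held 67.2% of the variance and placed the Tie2-negative arrays between -72.8 and -53.0, Tie2-positive replicates 3 and 2 at 35.6 and 41.2, and Tie2-positive replicate 1 at 109. The difference between the 3' and 5' control probe sets of Actb and Gapdh, a measure of RNA length, was 1.60 ± 0.19 (SD, n = 3) in the Tie2-positive and 1.91 ± 0.09 (SD, n = 3) in the Tie2-negative population on the log2 scale. An exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 arrays allow.

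Tek, the gene of the Tie2 antigen used for the sort, was higher by 6.07 ± 0.53 (SE, n = 3 per population) in the Tie2-positive population, with means of 10.91 ± 1.13 (SD) against 4.83 ± 0.06 (SD). Itgav was higher by 1.76 ± 0.26 (SE) in the probe set used, but by 0.37 and without a call over the mean of all its probe sets (limma adjusted p = 0.0894). Because both antigens defined the gates, these values check the labels and are not findings. Among antigens that were stained but not named in the titles, Cd200, a membrane glycoprotein, was higher by 4.20 ± 0.70 (SE), and Enpep, the peptidase recognised by the 6C3 antibody, fell by 2.38 ± 0.44 (SE). Eng (CD105, 1.46 ± 0.46, SE) and Thy1 (0.99 ± 0.30, SE) did not pass. In limma Eng passed with array weights (adjusted p = 0.0226) and without Tie2-positive replicate 3 (0.0421), where Enpep did not (0.0554). Of the 7 measured sort markers, 3 rose and 1 fell in limma, with adjusted p between 0.0103 and 0.0280, and 5 rose and 1 fell adjusted over the list alone. Limma's camera set test with a preset correlation of 0.01 gave the list as higher (adjusted p = 0.00476; adjusted p = 0.332 with an estimated correlation), which is no finding either, since the list holds the gate genes Tek and Itgav. The number past the threshold was 2 without Tie2-positive replicate 2 or Tie2-negative replicate 3, and 0 without Tie2-negative replicate 1 or 2. Ptprc, the gene of the CD45 antigen both gates excluded, gave values of 9.52, 10.41 and 9.42 in the Tie2-negative samples and of 4.87, 9.95 and 11.23 in Tie2-positive replicates 1, 2 and 3. Its change of -1.11 ± 1.52 (SE) did not pass (adjusted p = 0.650).

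The Tie2-positive cells carried high levels of vascular transcripts, and the Tie2-negative cells high levels of red-cell and early B-cell transcripts. Aplnr, the apelin receptor of endothelial cells, rose by 8.57 ± 0.40 (SE, n = 3 per population; limma adjusted p = 0.00330). The genes taken by the naming rule also included Fabp4, a fatty acid binding protein of capillary endothelium and fat (8.38 ± 0.60, SE), Epas1, which encodes the hypoxia-inducible factor HIF-2 alpha (7.10 ± 0.51, SE), and Nrp1, a co-receptor for vascular endothelial growth factor (6.74 ± 0.54, SE). The other 8 of the 12 named risers were Igfbp3, Fscn1, the type IV collagen gene Col4a1, the caveola gene Cavin2, Klhl4, the adhesion molecule Vcam1, the basement membrane gene Nid1 and Tcim, with log2 changes from 6.15 to 6.64. Epb42, a protein of the red-cell membrane skeleton, fell by 5.99 ± 0.57 (SE) on the log2 scale (limma adjusted p = 0.0103). Rag1, the recombinase of antigen receptor genes, fell by 5.81 ± 0.61 (SE), the B-cell coactivator Pou2af1 fell by 5.74 ± 0.65 (SE), and Rhag, a subunit of the red-cell Rh complex, fell by 5.67 ± 0.70 (SE). Tlcd4, Cldn13, Trim10, Pdia2, Rhd, the pre-B-cell gene Vpreb1, the haem synthesis gene Alas2 and Slc38a5 completed the 12, with log2 changes from -5.29 to -4.94. The deposited values carry no detection calls, and whether the lower population of a gene lay above background was not analysed (its mean was 4.22 for Aplnr and 3.78 for Epb42), so the sizes of large changes, and which is the largest, are those of the array values.

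Among 18193 genes, limma called 1345 (7.39%) at an adjusted p under 0.05, of which 884 rose and 461 fell in the Tie2-positive population. A change of at least 2-fold was met by 1189 of them (843 higher, 346 lower), and one of at least 8-fold by 282 higher and 60 lower genes. In all 1345 the 3 values of one population lay above the 3 of the other, which held for 7117 of all genes (39.1%, against 10% by chance). No called gene had another probe set called the opposite way. The size of a change depended on the probe set: over the mean of all probe sets of a gene, all 62 called genes of the naming rule kept their direction, 23 changes were smaller by over 1.5 times, and 6 genes (Alas2, Itgav, Notch4, Itgb3, Epcam and Pfkp) did not pass. With the replicate number as a block limma called 0 genes (smallest adjusted p 0.0521). With array weights limma called 4639 genes, and the genes that rose numbered 9 instead of 0 in the neutrophil list and 9 instead of 2 in the megakaryocyte list. The number of called genes depended on single arrays: it was 2148 without Tie2-positive replicate 1, 504 (375 higher, 129 lower) without Tie2-positive replicate 2 and 378 (251 higher, 127 lower) without Tie2-negative replicate 3, and the lower genes numbered 225 without Tie2-positive replicate 3. Without Tie2-negative replicate 1 or 2 limma called 0 genes (smallest adjusted p 0.0518 and 0.0607, with 4012 and 3980 genes at an unadjusted p under 0.05). Each count of list genes past the threshold over all genes given below was thus also 0 in those 2 fits and with the block. All 1345 genes kept an unadjusted p under 0.05 in each of the 6 fits that left out an array. They were chosen on these same arrays, and their direction could not change, because their populations did not overlap.

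**Figure D1:**
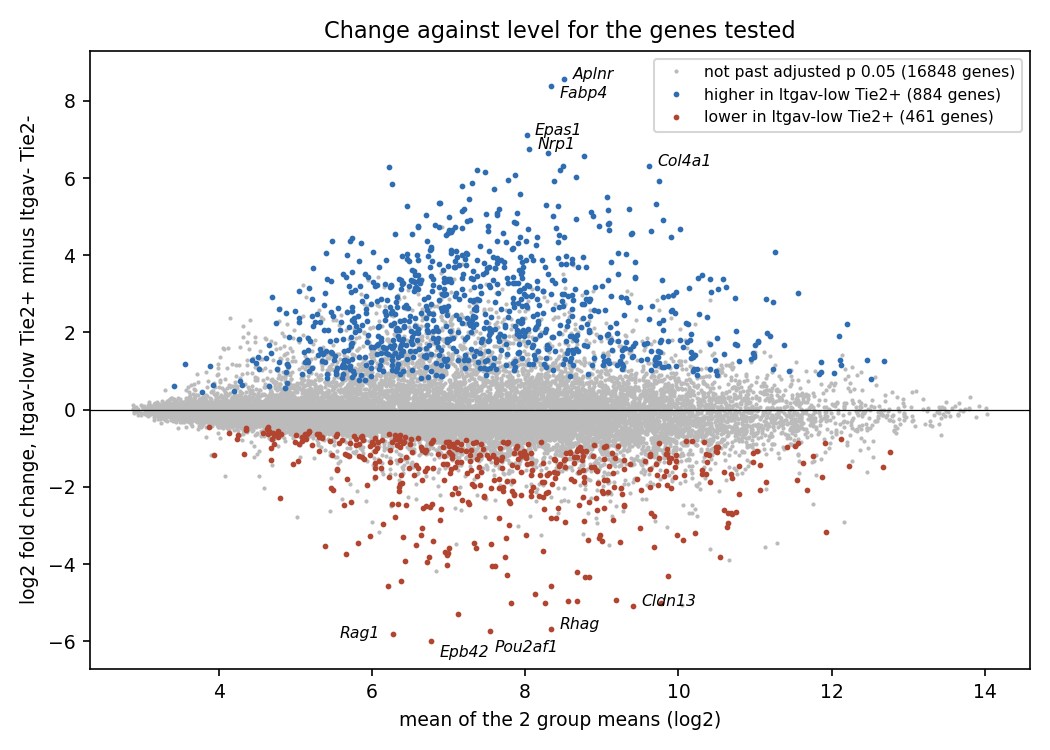
Log2 change (Tie2-positive minus Tie2-negative) against the mean level of 18193 genes (log2), each point a gene. Blue points are the 884 genes called higher, red points the 461 called lower, and grey points the 16848 that did not pass; Aplnr (8.57) and Epb42 (-5.99) lie at the ends.

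Genes of the pan-endothelial list rose together. Of 30 measured pan-endothelial genes, 19 rose, 0 fell and 11 did not pass over all genes, and all 30 rose adjusted over the list alone. Cdh5, the adhesion molecule of endothelial junctions, rose by 5.58 ± 0.61 (SE, n = 3 per population), the tight junction gene Cldn5 by 5.31 ± 0.75 (SE) and the surface sialomucin Emcn by 5.05 ± 0.85 (SE). Limma's camera called the list higher (adjusted p = 1.25e-21; adjusted p = 0.332 with an estimated correlation). Its median level was 11.15, 9.35 and 8.66 in Tie2-positive replicates 1, 2 and 3, and between 6.01 and 6.16 in the Tie2-negative samples. Among 16 arterial genes, 7 rose and 0 fell, and 13 rose adjusted over the list alone (camera adjusted p = 8.91e-09; adjusted p = 0.340 with an estimated correlation). They included Nrp1, the transcription factor Sox17 (5.37 ± 0.66, SE) and the growth factor Vegfc (4.78 ± 0.63, SE). Without probe sets that can match several transcripts, Sox17 was represented by another probe set and did not pass (1.68, adjusted p = 0.0880). Among 16 venous and sinusoidal genes, 10 rose and 0 fell, and 12 rose adjusted over the list alone (camera adjusted p = 2.66e-11; adjusted p = 0.332 with an estimated correlation). Aplnr, Vcam1 (6.21 ± 0.69, SE) and the cytokine receptor chain Il6st (5.10 ± 0.69, SE) led them. Of 5 lymphatic genes, Lyve1, a hyaluronan receptor also made by sinusoidal endothelium, rose by 2.51 ± 0.42 (SE) and was named after its value was seen, while Mmrn1 (2.39 ± 0.63, SE) and Reln (-2.01 ± 0.51, SE) did not pass, although Mmrn1 did with arrays centred on their medians (adjusted p = 0.0458) and Reln over the mean of all its probe sets (0.0462). Adjusted over the list alone 2 lymphatic genes rose and 1 fell, and camera did not call the list (adjusted p = 0.192). Without Tie2-negative replicate 3 the pan-endothelial, arterial and venous counts were 4, 4 and 4, and without Tie2-positive replicate 2 they were 9, 7 and 4. With Tie2-positive replicates 2 and 3 left out, a setting chosen after seeing the data, they were 30, 13 and 14. Without Tie2-negative replicate 3, 0 lymphatic genes rose and 1 fell.

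**Figure D2:**
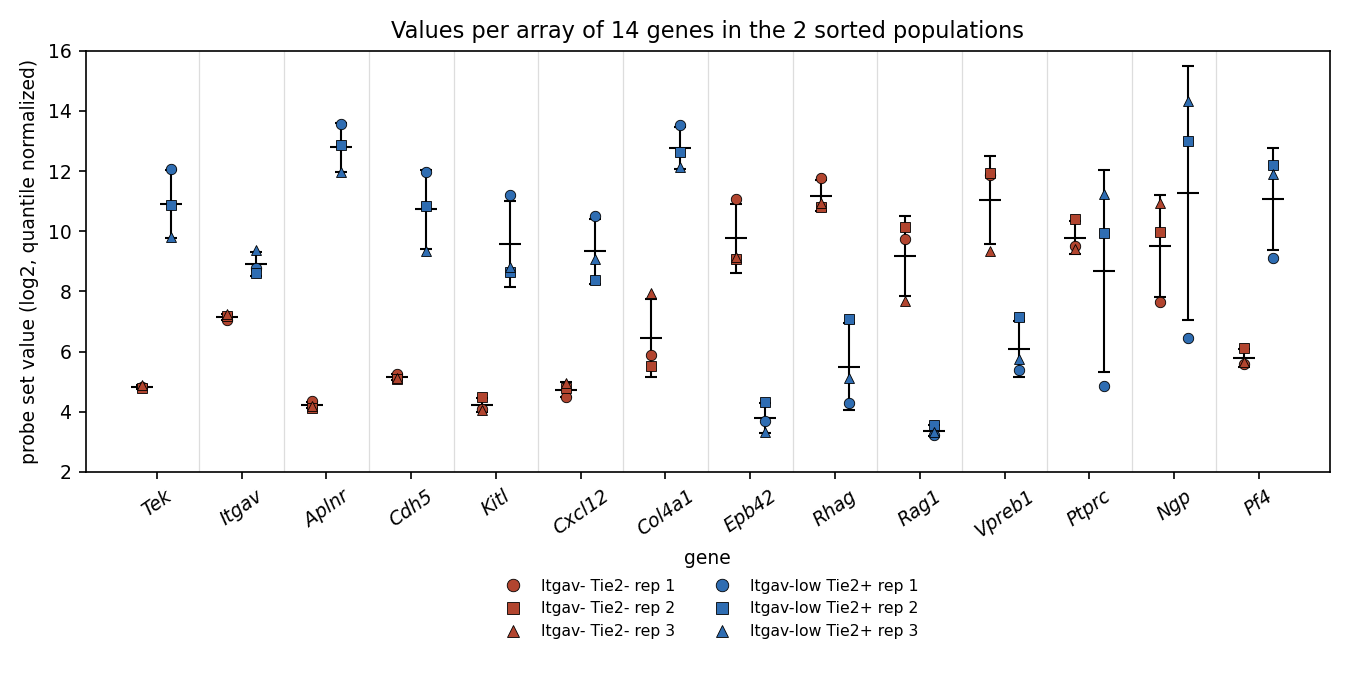
Quantile-normalized log2 values of 14 genes on each of the 6 arrays (symbols are arrays, red Tie2-negative and blue Tie2-positive), with the mean and SD of each population as bars. Endothelial, niche and basement membrane genes are higher on all 3 Tie2-positive arrays and Epb42, Rhag, Rag1 and Vpreb1 lower, while Ptprc runs from 4.87 to 11.23 and Ngp from 6.45 to 14.35 within the Tie2-positive population.

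Several factors that act on blood-forming cells were among the risers. All rises here are relative to Tie2-negative samples with high red-cell and early B-cell transcripts, and no other stromal population was compared. Kitl, the ligand of the Kit receptor, rose by 5.35 ± 0.66 (SE, n = 3 per population), the chemokine gene Cxcl12 by 4.59 ± 0.52 (SE) and the adhesion molecule Vcam1 by 6.21 ± 0.69 (SE). Over the mean of all probe sets of a gene these rises were 1.85, 2.34 and 2.74. Of 16 measured niche factors, 6 rose and 1 fell, with 7 rising and 1 falling adjusted over the list alone (camera adjusted p = 6.7e-05; adjusted p = 0.332 with an estimated correlation). The single decline was that of Il34, a ligand of the Csf1 receptor, which fell by 0.63 ± 0.11 (SE) and was named after its value was seen, but did not pass without Tie2-positive replicate 2 or 3 or Tie2-negative replicate 3. Within 24 genes of BMP, TGF-beta and Notch signalling, 7 rose and 0 fell, and 14 rose adjusted over the list alone (camera adjusted p = 7.81e-10; adjusted p = 0.332 with an estimated correlation). The 3 with the largest rises were Id2, an inhibitor of helix-loop-helix factors (4.52 ± 0.46, SE), the Notch ligand Jag1 (4.07 ± 0.53, SE) and the receptor Notch4 (3.63 ± 0.72, SE). Over the mean of all probe sets of a gene the signalling count was 3, and Notch4 did not pass (1.27, limma adjusted p = 0.0896). Of 14 basement membrane genes, 10 rose and 0 fell, and 12 rose adjusted over the list alone (camera adjusted p = 9.92e-11; adjusted p = 0.332 with an estimated correlation). They were led by Col4a1 (6.32 ± 0.68, SE), Nid1 (6.21 ± 0.62, SE; nidogen) and Col4a2 (5.11 ± 0.58, SE). Of 21 integrin subunits, 4 rose and 0 fell, both over all genes and adjusted over the list alone. These were the laminin-binding chain Itga6 (3.41 ± 0.43, SE), Itga8 (3.29 ± 0.28, SE), Itgb3 (2.84 ± 0.65, SE; a partner chain of integrin alpha V) and, named after its value was seen, Itga1 (2.56 ± 0.54, SE). Itgb3 lay near the threshold (adjusted p = 0.0482) and did not pass over the mean of all its probe sets (1.42, adjusted p = 0.0704), with all probe sets tested (0.0512), without the trend (0.0541) or with robust estimation (0.0508). Camera called the integrin list higher (adjusted p = 0.00125; adjusted p = 0.332 with an estimated correlation), but not with Tie2-positive replicates 2 and 3 left out (adjusted p = 0.104, chosen after seeing the data). Without Tie2-positive replicate 2 or Tie2-negative replicate 3 the signalling count was 3 in each case and the integrin count 2 in each case. The signalling count was 11 without Tie2-positive replicate 1 or 3, the integrin count 7 without Tie2-positive replicate 1, and the niche count 4 without Tie2-positive replicate 3.

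Red-cell genes were far lower in the Tie2-positive population. Of 17 measured erythroid genes, 9 fell and 0 rose, and 14 fell adjusted over the list alone (limma camera adjusted p = 8.77e-09; adjusted p = 0.336 with an estimated correlation). Epb42, Rhag and Trim10, a gene of erythroid differentiation (-5.02 ± 0.76, SE), led the list. The median erythroid level was 12.12, 10.81 and 10.95 in the Tie2-negative samples, although their gate excluded Ter119, and 6.13, 9.09 and 7.36 in Tie2-positive replicates 1, 2 and 3. Early B-cell genes moved the same way: 8 of 13 fell and 0 rose, and 11 fell adjusted over the list alone (camera adjusted p = 1.18e-07; adjusted p = 0.348 with an estimated correlation). Rag1, Pou2af1 and Vpreb1, a component of the surrogate light chain (a log2 change of -4.95 ± 0.79, SE, n = 3 per population), led them, and the median level of the list was between 7.83 and 10.12 in the Tie2-negative and between 5.50 and 5.96 in the Tie2-positive samples. Of 10 genes of T and NK cells, Cd2, an adhesion molecule, fell by 1.31 ± 0.25 (SE; named after its value was seen) and 0 rose, while Zap70 (-0.56 ± 0.23, SE) and Nkg7 (2.34 ± 1.25, SE) did not pass. Adjusted over the list alone 1 T and NK gene rose and 2 fell, and camera did not call the list (adjusted p = 0.212) except without Tie2-negative replicate 3 (adjusted p = 0.0373). Of 14 genes of antigen presentation and interferon response, 3 fell and 0 rose over all genes and adjusted over the list alone, with no camera call (adjusted p = 0.852). All 3 belong to class II antigen presentation: H2-Aa (-1.92 ± 0.27, SE), Cd74 (-1.21 ± 0.19, SE) and H2-Eb1 (-0.78 ± 0.15, SE). H2-Ab1, also of class II, did not pass. Over the mean of all its probe sets the change of H2-Aa was -0.66 (limma adjusted p = 0.0421). Without probe sets that can match several transcripts H2-Aa had no value. Without Tie2-negative replicate 3 the erythroid count was 4, without Tie2-positive replicate 2 the B-lineage count was 4, and the class II count was 0 and 1 without Tie2-positive replicate 2 and Tie2-negative replicate 3. Cd2 did not pass without Tie2-positive replicate 2 or 3.

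Neutrophil and platelet genes separated the Tie2-positive arrays from one another. The median of 13 neutrophil and monocyte genes was 6.01 in Tie2-positive replicate 1, 11.21 in replicate 2 and 13.34 in replicate 3, against 6.12, 7.58 and 8.15 in Tie2-negative replicates 1, 2 and 3. Ngp, a neutrophil granule protein (1.75 ± 2.02, SE, n = 3 per population), and the calcium-binding protein gene S100a8 (2.38 ± 1.70, SE) did not pass, and 0 of the 13 genes rose or fell, also adjusted over the list alone. At an unadjusted p under 0.05 limma also gave 0 of them. Camera called the list higher (adjusted p = 0.00264; adjusted p = 0.612 with an estimated correlation), but not without Tie2-positive replicate 3 (adjusted p = 0.130), and with Tie2-positive replicates 2 and 3 left out the direction turned (adjusted p = 0.0756, chosen after seeing the data). Without Tie2-positive replicate 1, 11 of the 13 genes passed. Of 10 megakaryocyte and platelet genes, 2 rose and 0 fell: the platelet chemokine gene Pf4 by 5.29 ± 0.79 (SE) and Clec1b, a platelet receptor for podoplanin, by 2.18 ± 0.49 (SE; named after its value was seen), which did not pass with values as deposited (adjusted p = 0.0518) or without the trend (0.0541). Adjusted over the list alone 5 rose (camera adjusted p = 0.00223; adjusted p = 0.473 with an estimated correlation), and over all genes 7 rose without Tie2-positive replicate 1, 1 without Tie2-positive replicate 3 and 0 without Tie2-negative replicate 3. The camera call of this list was also lost with Tie2-positive replicates 2 and 3 left out (adjusted p = 0.412). Of 11 stem and progenitor genes, 4 rose and 0 fell, and 4 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0401; adjusted p = 0.398 with an estimated correlation). The 4 were Cd34 (5.01 ± 1.02, SE), Procr (4.14 ± 0.72, SE; the endothelial protein C receptor), Mecom (3.77 ± 0.56, SE) and, named after its value was seen, Gata2 (2.68 ± 0.60, SE), each of which is also known from endothelial cells. Gata2 did not pass over the mean of all its probe sets (adjusted p = 0.0528). Without Tie2-positive replicate 1 the change of Gata2 was larger (3.365), while those of Cd34, Procr and Mecom were smaller (4.39, 3.361 and 3.135). Which cells gave the Gata2 values was not tested. Without Tie2-positive replicates 2 and 3, taken one at a time, 1 and 2 of the stem and progenitor genes rose, and without Tie2-negative replicate 3 none did (0). Their camera call was lost without Tie2-positive replicate 2 (adjusted p = 0.160), Tie2-positive replicate 3 (0.130) or Tie2-negative replicate 2 (0.0696), and its direction turned with Tie2-positive replicates 2 and 3 left out (adjusted p = 0.881). Of 13 macrophage genes 0 rose or fell, 2 rose adjusted over the list alone, and 2 were higher and 1 lower at an unadjusted p under 0.05 in limma (camera adjusted p = 0.355), with Laptm5 at -0.22 ± 1.23 (SE) and Ctss at -3.24 ± 1.13 (SE). Without probe sets that can match several transcripts Laptm5 was lower (-1.37, adjusted p = 0.0397). Of 9 osteoclast genes, Itgb3 rose and Acp5 fell over all genes and adjusted over the list alone (camera adjusted p = 0.977). Acp5, tartrate-resistant acid phosphatase, is also made by cells other than osteoclasts and showed a log2 change of -3.67 ± 0.61 (SE). Itgb3 did not pass without Tie2-positive replicate 2 or 3, and neither gene without Tie2-negative replicate 3, while without Tie2-positive replicate 1, 2 macrophage genes rose and without Tie2-positive replicate 3, 1 fell.

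**Figure D3:**
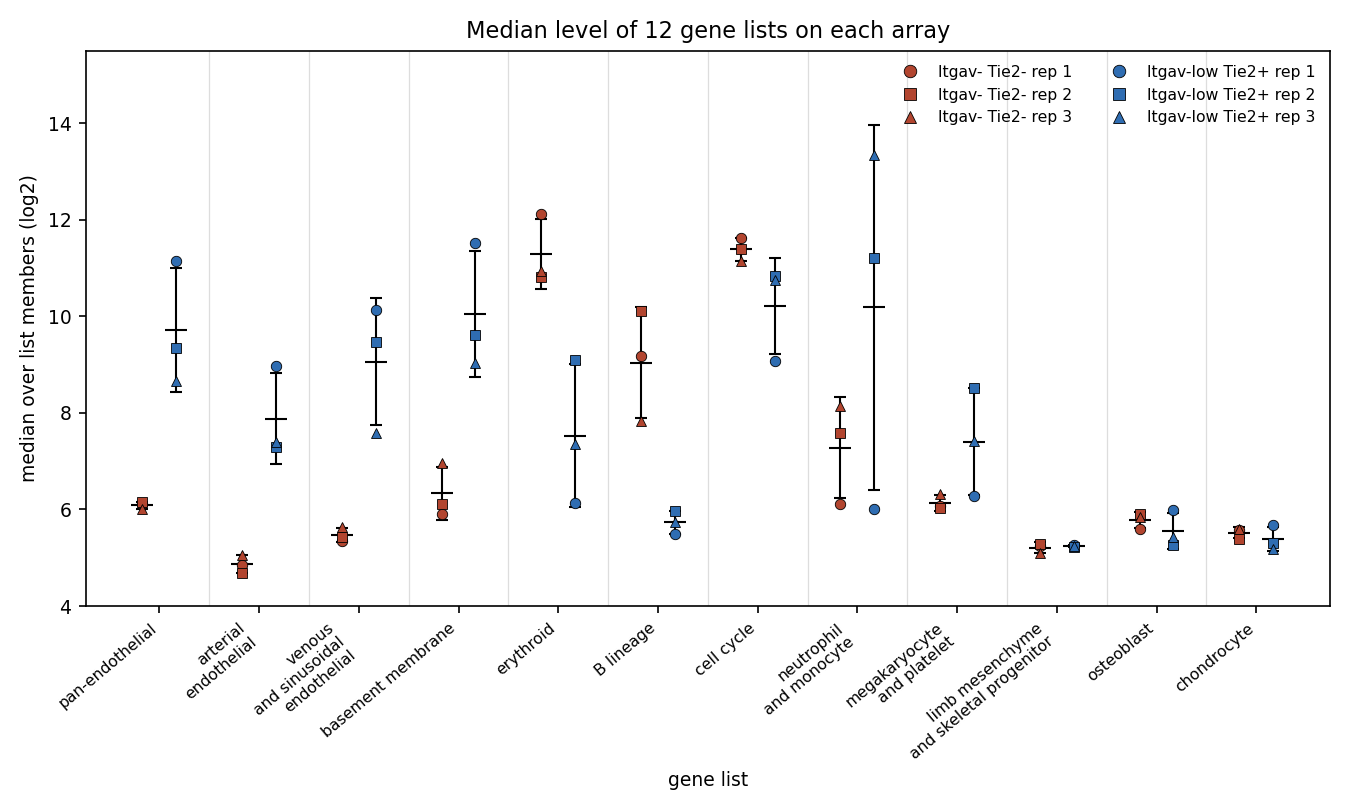
Median log2 level of 12 gene lists on each of the 6 arrays (symbols are arrays, red Tie2-negative and blue Tie2-positive), with the mean and SD of each population as bars. Endothelial and basement membrane lists lie higher on every Tie2-positive array and erythroid and B-lineage lists lower, the neutrophil median runs from 6.01 to 13.34 within the Tie2-positive population, and the skeletal lists stay between 5.09 and 5.98 on all arrays.

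Few genes of the skeletal lineages passed, and camera called none of the limb mesenchyme, osteoblast and cartilage lists with all arrays weighted equally. None of 18 limb mesenchyme and skeletal progenitor genes passed, also adjusted over the list alone (0 higher and 1 lower at an unadjusted p under 0.05 in limma; camera adjusted p = 0.945), with Msx1 at -0.33 ± 0.21 (SE, n = 3 per population) and Lepr at 0.55 ± 0.37 (SE). Of 12 osteoblast genes, Alpl, alkaline phosphatase, fell by 0.93 ± 0.21 (SE; named after its value was seen) and 0 rose (camera adjusted p = 0.852), while Col1a2 (0.85 ± 0.37, SE) and Col1a1 (-0.18 ± 0.42, SE) did not pass. Of 20 cartilage genes, Sox6 fell by 3.81 ± 0.64 (SE) and 0 rose (camera adjusted p = 0.212). Sox6 is a cartilage transcription factor that also acts in red-cell maturation. The cartilage list was called lower without Tie2-positive replicate 1 (adjusted p = 0.0012) and with array weights (adjusted p = 0.0277). With array weights 1 limb mesenchyme, 2 osteoblast and 4 cartilage genes fell and 1 osteoblast gene rose. All 3 Tie2-positive values lay below the 3 Tie2-negative ones for 3 limb mesenchyme, 2 osteoblast and 3 cartilage genes and above them for 0, 1 and 0. For both directions together the share was 39.1% over all genes, against 10% by chance. These lists thus separated less often than genes at large. Their medians lay between 5.09 and 5.98 on every array, below the median of all gene values (6.55). Whether their genes lay above background was not analysed, so a difference in them is not excluded. Of 12 fibroblast and tendon genes 0 passed, with 1 higher and 1 lower at an unadjusted p under 0.05 in limma (camera adjusted p = 0.852), and Col3a1 stood at 2.53 ± 1.06 (SE) and Dpt at 1.48 ± 1.02 (SE). These counts were the same adjusted over each list alone. Of 12 pericyte and smooth muscle genes, Cnn1, a calponin of smooth muscle, fell by 0.56 ± 0.13 (SE; named after its value was seen) and 0 rose, while 2 rose and 1 fell adjusted over the list alone. With array weights 5 of the 12 rose and 1 fell. Camera called the pericyte list higher (adjusted p = 0.0135; adjusted p = 0.332 with an estimated correlation), but not without probe sets that can match several transcripts (adjusted p = 0.156). Abcc9 (2.09 ± 0.71, SE) and Acta2 (1.06 ± 0.61, SE) did not pass, and without those probe sets Acta2 was represented by another probe set and was lower (log2 change -0.90, adjusted p = 0.0132). Of 6 fat-cell genes, Pparg, a nuclear receptor also present in capillary endothelium, rose by 3.34 ± 0.72 (SE) and 0 fell, also adjusted over the list alone (camera adjusted p = 0.253). Of 18 skeletal muscle genes, Tnnt1 rose by 2.02 ± 0.37 (SE) and Mylpf fell by 1.54 ± 0.32 (SE), with 1 rising and 3 falling adjusted over the list alone (camera adjusted p = 0.945). Of 8 Schwann cell genes 0 passed, also adjusted over the list alone, with 1 higher and 2 lower at an unadjusted p under 0.05 in limma (camera adjusted p = 0.316), and Mbp stood at -1.51 ± 0.71 (SE) and Sox10 at -0.53 ± 0.19 (SE). Of 9 epidermal genes, Epcam, an epithelial adhesion molecule also found on erythroid progenitors, fell by 0.88 ± 0.20 (SE) and 0 rose, and 2 fell adjusted over the list alone (camera adjusted p = 0.828). Without probe sets that can match several transcripts Epcam was represented by another probe set and its change was -0.046 (adjusted p = 0.885), and it did not pass with values as deposited (adjusted p = 0.0857) or arrays centred on their medians (0.102) either. Near the threshold, Alpl did not pass with all probe sets tested (adjusted p = 0.0548) and Cnn1 without the trend (0.0671), while Abcc9 passed over the mean of all its probe sets (3.89, adjusted p = 0.0350). Without Tie2-positive replicate 2 none (0) of the single genes that passed in these lists did so, and without Tie2-negative replicate 3 Alpl, Cnn1, Pparg, Mylpf and Epcam did not. Without Tie2-positive replicate 3 Alpl, Cnn1, Tnnt1, Mylpf and Epcam did not pass, and 2 pericyte genes and 1 Schwann cell gene rose. Without Tie2-positive replicate 1 Cnn1 did not pass, 2 cartilage genes and 1 fibroblast gene fell, 2 genes each of the fibroblast, pericyte, skeletal muscle and epidermal lists rose, and 1 osteoblast gene rose.

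Stress and early response genes were higher in the Tie2-positive population. Of 19 such genes, 9 rose and 0 fell, and 14 rose adjusted over the list alone (limma camera adjusted p = 3.1e-09; adjusted p = 0.332 with an estimated correlation). Klf4, a transcription factor induced by shear stress and dissociation, rose by 3.84 ± 0.68 (SE, n = 3 per population), and the heat shock genes Hspa1a and Hspa1b by 3.69 ± 0.56 (SE) and 3.17 ± 0.46 (SE). The stress count was 5 without Tie2-positive replicate 2, 4 without Tie2-positive replicate 3 and 3 without Tie2-negative replicate 3. All 23 cell cycle genes had a negative log2 change, with a median of -1.22, but 0 passed over all genes or adjusted over the list alone, and 10 were lower at an unadjusted p under 0.05 in limma. With array weights 5 of the 23 fell. The replication genes Mcm7 (-1.22 ± 0.53, SE) and Pcna (-0.99 ± 0.37, SE) had adjusted p values of 0.185 and 0.144. Camera called the cell cycle list lower (adjusted p = 6.7e-05; adjusted p = 0.602 with an estimated correlation). Its median level was 9.08, 10.83 and 10.76 in Tie2-positive replicates 1, 2 and 3, of which replicate 1 also had the lowest neutrophil and erythroid medians. Of the 23 genes, 8 fell without Tie2-positive replicate 1, 1 fell without Tie2-positive replicate 3, and 21 fell with Tie2-positive replicates 2 and 3 left out, a setting chosen after seeing the data. Of 22 genes of oxidative phosphorylation 0 passed, also adjusted over the list alone, with 1 lower at an unadjusted p under 0.05 in limma (camera adjusted p = 0.945), and Uqcrb stood at -0.13 ± 0.10 (SE) and Cox5b at -0.30 ± 0.15 (SE). Of 13 glycolysis genes, 2 rose and 1 fell, and 4 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.180, and 0.0419 without Tie2-positive replicate 1). Pkm, pyruvate kinase, rose by 2.25 ± 0.35 (SE), and of the phosphofructokinase genes Pfkp rose by 1.45 ± 0.30 (SE) and Pfkm fell by 1.80 ± 0.24 (SE). Over the mean of all its probe sets Pfkp did not pass (0.53, adjusted p = 0.0835). Without Tie2-positive replicate 2 neither Pkm nor Pfkp passed, without Tie2-positive replicate 3, 1 glycolysis gene rose, and without Tie2-negative replicate 3 none (0) passed.

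Over the 31 lists, camera with the preset correlation called 13 higher (the sort markers, set in part by the gates, among them) and 3 lower at an adjusted p under 0.05, and 0 were called with an estimated correlation (3 at an unadjusted p under 0.05). Camera with the preset correlation also called 8 to 12 lists in splits of the arrays that mixed the populations. Limma's fry, which tests whether the genes of a list move one way on balance, called 14. In lists without a camera call the median, mean and test did not always share a sign. The osteoblast median was -0.20 and its mean 0.09 with camera lower. The fibroblast and tendon median was -0.04 and its mean 0.24 with camera higher. The epidermal median was -0.09 and its mean 0.12 with camera lower, and the osteoclast median was -0.16 and its mean 0.01 with camera lower. For the fibroblast and tendon, skeletal muscle, and antigen presentation lists fry gave the direction lower and camera higher.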

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

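Leaving out Tie2-positive replicates 2 and 3 together was chosen after seeing the data; all other alternatives were fixed before. Apart from the estimated correlation, 10 of the 31 gene lists kept their call and direction in every alternative run for them: the sort markers (set in part by the gates and so no finding), pan-endothelial, arterial, venous and sinusoidal, BMP, TGF-beta and Notch signalling, niche factor, basement membrane and stress lists (higher), and the erythroid and B-lineage lists (lower). The counts of called genes stayed within 1.5 times the reported ones under the other scalings, the dim filter, the probe set choices and the other eBayes settings, with 65.7% of called genes higher as reported, 69.8% with values as deposited and 74.7% with arrays centred on their medians.

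The counts moved with the weight given to single arrays. Leaving out 1 array gave 0 to 2148 called genes (higher 0 to 1496, lower 0 to 652), and at least 2-fold 0 to 1733 (higher 0 to 1296, lower 0 to 437), with 0 to 4 sort markers. Array weights gave 4639 called genes (2177 higher, 2462 lower; 46.9% higher) and 1990 at least 2-fold (1415 higher, 575 lower). Leaving out Tie2-positive replicates 2 and 3 gave 3637 (1995 higher, 1642 lower) and 3512 at least 2-fold (1925 higher, 1587 lower). Of the 1345 genes called, 1342 were called again with array weights. The direction of these genes could not change in either setting, because their populations did not overlap. The cause was not tested.

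With the replicate number as a block, 0 genes and 0 sort markers passed, also at least 2-fold and in each direction (smallest adjusted p 0.0521; 5080 genes at an unadjusted p under 0.05). Same-numbered samples deviated together with correlations of 0.14, 0.0050 and 0.19 for replicates 1, 2 and 3, and differently numbered ones with correlations from -0.16 to 0.055. Tie2-positive replicates 1 and 3 but not 2 (0.055 with Tie2-negative replicate 3) correlated best with their own number. With 3 samples per population these values do not settle whether the numbers pair the samples.

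With an estimated correlation 0 of the 16 called lists kept their call. The adjusted p was 0.332 for the sort marker, pan-endothelial, venous and sinusoidal, BMP, TGF-beta and Notch signalling, niche factor, basement membrane, integrin, pericyte and stress lists, 0.340 for arterial, 0.336 for erythroid, 0.348 for B lineage, 0.612 for neutrophil, 0.473 for megakaryocyte, 0.398 for stem and progenitor and 0.602 for cell cycle. The estimated correlation ran up to 0.917 (neutrophil), but was -0.0095, -0.037 and -0.056 for the sort marker, integrin and pericyte lists, so a higher correlation does not account for the loss of those calls. Fry added the lymphatic (0.0409) and Schwann cell (0.00993) lists and lost the neutrophil (0.368), megakaryocyte (0.173), stem and progenitor (0.148) and cell cycle (0.185) lists. With Tie2-positive replicates 2 and 3 left out, the integrin (0.104) and megakaryocyte (0.412) calls were lost, and the neutrophil (0.0756) and stem and progenitor (0.881) lists turned lower without a call. The stem and progenitor call was also lost with median-centred arrays (0.0532), the dim filter (0.0852) and without x_at and s_at probe sets (0.141), and the pericyte call in the last (0.156). Array weights added the cartilage list (0.0277). Leaving out 1 array moved the adjusted p between 0.0012 and 0.732 for cartilage, 2.85e-10 and 0.130 for neutrophil, 5e-05 and 0.160 for stem and progenitor, 0.0373 and 0.394 for T and NK, and 0.0419 and 0.420 for glycolysis. The cause was not tested for these.

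Of 87 named genes, 8 changed sign in some alternative, none of them called with all arrays: Acta2, Col1a1, Dpt, Laptm5, Ngp, Nkg7, Ptprc and S100a8. Acta2 alone was called with the other sign (-0.90 without x_at and s_at probe sets, where another probe set stands for it). All 62 called named genes kept an unadjusted p under 0.05 when any 1 array was left out. Their direction could not change there, because their populations did not overlap. The exact p of the 3' to 5' difference was 0.1 for Actb alone and for Gapdh alone. The deposited values carry no detection calls, so which genes lay above background was not analysed here.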

Other observations

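The 3 gene groups in the next paragraph, the comparison of RNA length within the Tie2-positive population and the tests of carry-over, of the CD45 gate and of even dilution were chosen after the values were seen; the other tests were planned before.

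All 7 measured enzymes of haem synthesis fell in the Tie2-positive cells, with a median log2 change of -3.04. Alas2, the erythroid entry enzyme of the pathway, had the largest decline (-4.95 ± 1.13, SE, n = 3 per population; limma adjusted p = 0.0483) and Urod the smallest (-1.76 ± 0.38, SE). In limma 4 of the 7 passed without Tie2-positive replicate 3 or without Tie2-negative replicate 3. None (0) of the genes in these 3 groups passed without Tie2-negative replicate 1 or 2, and no group was tested as a set. Coat genes of caveolae, the membrane pits abundant in endothelium, were higher: Cav1 by 5.93 ± 0.62 (SE), Cavin1 by 3.78 ± 0.65 (SE), Cavin2 by 6.31 ± 0.83 (SE) and Cavin3 by 4.64 ± 0.61 (SE), while Cav2 (2.98 ± 0.73, SE) did not pass (adjusted p = 0.0567). The signalling chains of the IL-6 receptor family were higher as well. Il6st rose by 5.10 ± 0.69 (SE), Lifr by 4.74 ± 0.69 (SE) and Osmr by 4.54 ± 0.81 (SE). Over the mean of all probe sets of a gene these rises were 2.72, 2.28 and 1.51. Il6ra (-0.30 ± 0.17, SE) and Cntfr (-0.52 ± 0.19, SE), which also belong to the family, did not pass. Adjusted over this group alone 3 rose and 1 fell. Alas2, Cavin1 and Osmr did not pass without Tie2-positive replicate 2 or without Tie2-negative replicate 3, and Cav2 passed without Tie2-positive replicate 1 (adjusted p = 0.0318) and with values as deposited (0.0470). Alas2 lay near the threshold and did not pass with all probe sets tested (0.0509), without the trend (0.0547) or with robust estimation (0.0508), and over the mean of all its probe sets Cavin1 did not (1.40, adjusted p = 0.0504).

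Of the 10 splits of the 6 arrays into 3 and 3, 1 (the real one) gave as many called genes, 1345 against 0 in the highest other, and 1 gave as many at least 2-fold, 1189 against 0. For the called lists, 1 split gave as many, 16 against 12 in the highest other. Each other split called at least 8 lists, although its sides mixed the populations and it called 0 genes. A camera call at the preset correlation thus also arose where the populations were mixed. These splits are too few for a share under 0.05.

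Tie2-positive replicate 1 stood apart from replicates 2 and 3. A difference in RNA length stays open: its 3' to 5' difference of 1.805 lay within the range of the other 5 arrays, but the Tie2-negative arrays alone filled that range upwards, and the values of replicates 2 and 3 were lower (1.56 and 1.44). A different content of other cells stays open as a candidate explanation: 13 of 13 neutrophil and monocyte genes were lower in it than in both other arrays, by a median of -6.26. Of the 884 genes called higher, 713 were higher in replicate 1 than in replicates 2 and 3 and 67 were lower than in both. A difference between litters was not tested.

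Neutrophil genes were high in Tie2-positive replicates 2 and 3. In both samples all 13 genes, of which 1 also stands in another list, lay above every Tie2-negative array. The median excess was 2.45 for the lower of the 2 samples. These values argue against carry-over of the Tie2-negative cells as the mixture that was measured. Carry-over of a neutrophil-rich part of those cells could not be told apart by them. Blood cells that passed the CD45 gate remain a candidate source: Ptprc was at least 5.08 higher in both samples than in replicate 1, and Ngp reached 13.01 and 14.35. The gate would remove such cells, and Ptprc RNA was also present in the Tie2-negative samples (9.42 to 10.41). Blood-forming cells that carry Tie2 themselves could give the same values and were not tested apart.

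Endothelial genes differed between Tie2-positive replicates 2 and 3 in an uneven way. From replicate 2 to 3 the median change was -1.79 over the 10 called venous and sinusoidal genes and 0.13 over the 7 called arterial genes, a difference of -1.91 (exact two-sided permutation p over genes = 0.00437, genes not being independent). Even dilution of the same endothelial mixture would move both groups alike only if the other cells present lacked these transcripts, which was not tested. The comparison sets replicate 2 against replicate 3 without further arrays, and the genes were called on these same arrays. It therefore cannot decide whether dilution took place. A different share of sinusoidal against arterial vessels in the 2 samples may explain the difference between the gene groups. Expression of some of these genes by the other cells may do so too, and neither was tested.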
